A study of Homo sapiens with 12 samples.

How the data were processed

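RNA of human stromal cells, given as fibroblasts in the labels, was measured in 12 libraries, 3 for each of vehicle, avelumab, atezolizumab and durvalumab after 24 h. Per the labels' protocols, total RNA was isolated from cultured cells with a column kit, and stranded libraries of polyA RNA were prepared with Illumina's TruSeq kit. Groups and replicate numbers follow the labels of the single samples. The design text names other antibodies (pembrolizumab and nivolumab), and this was not resolved. Aligner, counting tool and their versions are not given in the sources used here.

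The authors deposited 1 table per library, with 153438 RefSeq transcripts, 3258 of them without a RefSeq accession in the table. The genome build is hg38 per the submitters' processing notes. Per the file headers, the count columns hold total and unique reads per transcript, as whole numbers that are not normalized, where unique reads fit 1 transcript. The authors' TPM values are relative transcript abundances, with length taken into account, per the file headers. The authors' RPKM values are total reads divided by transcript length and by a read total of the library, per the file headers, and the column named expression value equals the RPKM. Between 6.69% and 8.5% of the reads in the RPKM denominator lie outside the table. Counts from 1 to 20 of genes with 1 transcript were even in 59.3% to 62.4% of cases, so that low counts may hold both reads of a pair and overstate the number of fragments. TPM and RPKM were used only to check the units.

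Total reads were summed over transcripts to 38614 genes. Reads shared between transcripts enter these sums as the authors divided them, so near-identical genes are uncertain, and unique reads made up 24.0% to 25.0% of the total. The 10 most abundant genes held 6.28% to 6.88% of reads. Depth ranged from 66525258 to 150616357 reads per library, so the spread between libraries, and not counting error, limits the precision of abundant genes. Of these genes 17869 passed edgeR's filter (filterByExpr, minimum count 10, minimum total 15).

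The test for each gene was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM scaling in 1 fit of all 12 libraries, for 6 comparisons, at a Benjamini-Hochberg adjusted p of 0.05. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1, so none was used for single genes. Gene lists, 34 in number, were tested with camera (limma 3.58.1) on the same fit, with a preset correlation of 0.01, where at least 5 genes were tested, which held for 30 lists. List p-values were adjusted over the lists of a comparison. Camera with a correlation estimated for each list and fry were alternatives. DESeq2 1.42.0 and limma-voom were run as other tests. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.

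The lists, the rule for named genes, the tests and the alternatives (10 for counts of genes, 5 for counts of lists) were fixed before the data were examined. The rule took, for each comparison with vehicle, the 10 genes with the largest rise and the 10 with the largest fall among protein-coding genes past the threshold whose groups did not overlap and with at least 5 CPM in the higher group. It took 5 and 5 between antibodies, up to 4 called members of each list, and CD274 always. Where no member of a list was called, its most abundant members could be given. Not every gene that the rule allows is described. These alternatives were other scalings, other filters, other tests, unique reads, the 6 libraries of a comparison alone, the replicate number as a block, and leaving out each library. The 3 added after seeing the data were a correction for GC content and transcript length, the fit without atezolizumab replicate 2, and that fit with an estimated correlation. The correction used a lowess curve (span 0.3) per library over genes with a mean log2 CPM of at least 1. GC content was known for 15822 of the tested genes (88.5%, and 98.1% of protein-coding genes).

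The tests were tested on simulated data drawn from the vehicle means and the library sizes of the real libraries. At each fold size 50 genes were changed. Of genes changed 1.5-fold, 94% were recovered for avelumab and atezolizumab and 92% for durvalumab, each against vehicle. Of genes changed by 0.32 on the log2 scale, 66% were recovered for avelumab, 74% for atezolizumab and 72% for durvalumab. The changed genes were drawn at random from genes with at least 5 CPM in vehicle, so these shares do not cover genes with lower levels. No share was computed for genes with a wide spread between libraries, such as IL1B. A list shifted by 0.3 on the log2 scale was called, with 0 other lists called. Genes were drawn independently there, so this cannot show how camera behaves where the genes of a list vary together.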

Results

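RNA was measured by sequencing in 12 libraries of human stromal cells, given as fibroblasts in the labels, from work on the renal tumour microenvironment. The cells had been kept for 24 h with vehicle or with 1 of 3 antibodies, avelumab, atezolizumab or durvalumab, with 3 libraries per group. These antibodies bind PD-L1, the product of CD274, which holds back T cells through the receptor PD-1. The design text of the series instead names pembrolizumab and nivolumab, which bind PD-1 itself. The groups below follow the labels of the single samples, and the conflict stays open. Doses are not given in the sources used here, and no source says that the replicates were separate cultures, so each p-value measures the spread between these libraries, which may be technical. Libraries held from 66525258 reads on annotated transcripts (atezolizumab replicate 3) to 150616357 reads (atezolizumab replicate 1), and 17869 genes were tested. Levels are given in CPM (library-scaled counts after TMM), as mean ± SD over the 3 libraries of a group.

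The libraries carried the transcripts of fibroblasts. In vehicle, the intermediate filament gene VIM stood at 5872 ± 92.7 CPM, and COL1A1, a chain of type I collagen, at 2961 ± 77.2 CPM (n = 3). The median of 36 leukocyte markers was 0.0238 CPM in vehicle, and PTPRC, which encodes the leukocyte surface protein CD45, had 0 to 8 reads per library. The renal epithelial transcription factor PAX8 was at 16.8 ± 0.924 CPM in vehicle. FCGR2A, a receptor for the constant part of antibodies, was at 0.413 ± 0.0849 CPM. CD274 itself was detected at 4.25 ± 0.238 CPM in vehicle, 4.36 ± 0.396 in avelumab, 4.15 ± 1.48 in atezolizumab and 3.61 ± 0.549 in durvalumab (n = 3 each). It lies on the plus strand of chromosome 9 at 5450503 to 5470567 (hg38). Its log2 change from vehicle was 0.04 (SE 0.19) in avelumab, -0.04 (SE 0.19) in atezolizumab and -0.23 (SE 0.19) in durvalumab, with adjusted p of 0.973, 0.91 and 0.45 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Without atezolizumab replicate 2 the change in atezolizumab was -0.37, with an adjusted p of 0.0342 by edgeR's quasi-likelihood test.

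Groups did not hold together equally well. On the first principal component (26.3% of the variance) all vehicle and avelumab libraries lay at one end, from -14.2 to -23.7, and the 3 durvalumab libraries at the other, from 19.7 to 29.5. Atezolizumab replicates 1 and 3 lay at 21.1 and 28.1 with durvalumab, and atezolizumab replicate 2 at -15.4 with vehicle and avelumab. The library whose expression correlated best with that of atezolizumab replicate 2 was avelumab replicate 3 (r = 0.9966 across genes, which are not independent). Vehicle and avelumab share 1 of the 2 prefixes of the deposited file names, and atezolizumab and durvalumab share the other. The sources used here do not say what the prefixes mark, so whether they bear on the conflict over the antibodies is open too, and they were not used for grouping. A difference between 2 sequencing runs can therefore not be told apart from the antibody in any comparison across the prefixes.

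**Figure D1:**
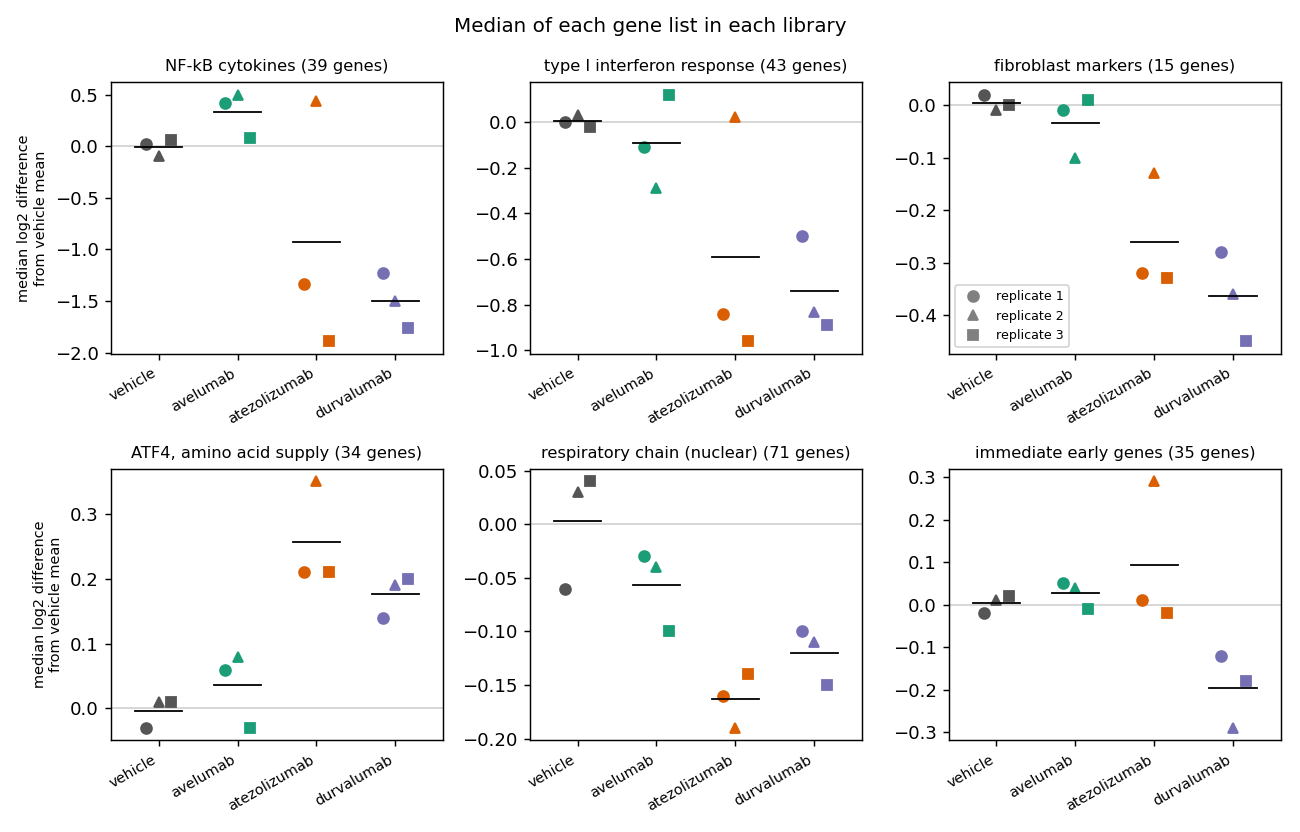
Median log2 difference from the vehicle mean of the genes of 6 lists (vertical axes), for each of the 12 libraries (points, by group on the horizontal axis), where lines mark the mean of each group. On the cytokine list, atezolizumab replicate 2 lies at 0.44, while replicates 1 and 3 lie at -1.34 and -1.89, beside durvalumab at -1.23 to -1.76.

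The comparison of avelumab with vehicle asked what this antibody did to the cells, and both groups share a file-name prefix. No single gene passed the threshold: edgeR's quasi-likelihood test called 0 of 17869 genes, with a lowest adjusted p of 0.19 after Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 1674 genes, DESeq2 called 71 and limma-voom 0. As a group, the cytokine and NF-kappa-B target genes, which carry inflammatory signals, were higher, with a positive change in 37 of 39 genes and a median log2 change of 0.34 (camera adjusted p = 0.00118, adjusted p = 0.901 with an estimated correlation). Their most abundant members were SOD2, a mitochondrial superoxide dismutase, at 2036 ± 248 against 1772 ± 88.1 CPM, and the neutrophil attractant CXCL8 at 1283 ± 357 against 926 ± 81.4. The inflammatory cytokine IL1B had 703 ± 214 against 420 ± 66.0 CPM, a log2 change of 0.74 (SE 0.73). The medians of the list per library were 0.42, 0.50 and 0.08 in avelumab replicates 1, 2 and 3.

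Genes of the respiratory chain that are encoded in the nucleus were lower by a median log2 change of -0.06, in 60 of 71 genes (camera adjusted p = 2.47e-06, adjusted p = 0.901 with an estimated correlation). With the GC and length correction the median was -0.02 and the call ended (adjusted p = 0.148). Ribosomal protein genes had a median of -0.02 (camera adjusted p = 0.0415), and glycolysis and unfolded protein response genes each had 0.04 (0.0285 for both lists), all with adjusted p = 0.901 with an estimated correlation. These 3 calls did not hold without single libraries. Without avelumab replicate 2 the adjusted p was 0.303 for glycolysis and 0.318 for the unfolded protein response. Without vehicle replicates 1 and 2 it was 0.138 and 0.0607 for glycolysis and 0.123 and 0.142 for the unfolded protein response. The ribosomal list had 0.955 without avelumab replicate 3, 0.28 without vehicle replicate 2 and 0.749 without vehicle replicate 3. The correction gave 0.148 for glycolysis and 0.701 for the ribosomal list, and 0.00197 for the unfolded protein response, with a median of 0.06. No gene of these 4 lists or the cytokine list passed alone or adjusted over the list alone, and fry called 0 of 30 lists. Groups did not overlap for 18.3% of genes, where chance gives 10% on average. Genes vary together, so this share can lie far from 10% by chance, and its spread was not computed for any comparison. Without avelumab replicate 1 the count was 1 gene, and without atezolizumab replicate 2, which enters the estimate of the spread, it was 11.

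Cells given atezolizumab showed higher levels of amino acid stress genes, targets of the transcription factor ATF4, and lower levels of genes for respiration and glycolysis and of fibroblast markers. Camera called each of these 4 lists, and each call was lost with an estimated correlation (adjusted p from 0.138 to 0.454). The respiratory list had a median log2 change of -0.17, and other coding genes matched to it on length and GC content had -0.11. The matched genes were longer, with a median of 1267 against 1000 bases, so the match on length was incomplete. ASNS, which makes asparagine, rose 2.02-fold, from 15.7 ± 1.04 to 31.7 ± 1.75 CPM (log2 change 1.01, SE 0.06, n = 3). SLC7A11, the cystine importer, rose 1.96-fold to 76.5 ± 12.1 CPM, and SLC7A5, an importer of large neutral amino acids, rose 1.71-fold to 77.8 ± 7.37 CPM. S100A4, a calcium-binding protein of fibroblasts, fell from 19.7 ± 1.12 to 10.4 ± 0.822 CPM. The changes were small for most genes: 3801 genes passed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 1797 higher and 2004 lower (2068 higher and 1712 lower when scaled by library totals alone), with a median absolute log2 change of 0.23 and 69 genes changed at least 2-fold.

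Of 34 genes of this ATF4 list, 21 rose and 1 fell (23 and 1 adjusted over the list alone), with a median log2 change of 0.25 (camera adjusted p = 1.69e-20, adjusted p = 0.138 with an estimated correlation). PSAT1, an enzyme of serine synthesis, rose by 0.69 (SE 0.06). ATF3, a stress-induced repressor, was the member that fell, by 0.38 on the log2 scale. Without replicate 2, 21 rose and 5 fell, with DDIT4 at -0.49 (SE 0.08), GDF15 at -0.35 (SE 0.08), WARS at -0.18 (SE 0.04) and DDIT3 at -0.13 (SE 0.05) beside ATF3 at -0.58 (SE 0.06), named after their values were seen. The list stood higher in each of the 3 libraries, with medians of 0.21, 0.35 and 0.21 in replicates 1, 2 and 3. The other genes with the highest rises were KRTAP2-3, a hair keratin-associated protein (1.09, SE 0.13), the adhesion receptor ADGRG6 (0.95, SE 0.23), the sphingosine phosphate receptor S1PR1 (0.83, SE 0.14), the peptide hormone gene ADM2 (0.81, SE 0.10), SAMD12 (0.76, SE 0.13), the bicarbonate transporter SLC4A4 (0.72, SE 0.15) and SCIN, which severs actin filaments (0.70, SE 0.17).

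Respiratory chain genes fell in 42 of 71 cases and rose in 0 (48 and 1 adjusted over the list alone), with a median log2 change of -0.17 (camera adjusted p = 7.77e-17, adjusted p = 0.428 with an estimated correlation). NDUFB5, a subunit of complex I, fell by 0.42 on the log2 scale (SE 0.05, to 37.5 ± 1.34 from 50.5 ± 2.41 CPM), and NDUFA4 by 0.38 (SE 0.04). Of 76 ribosomal protein genes, 38 fell and 0 rose (43 and 1 adjusted over the list alone), by a median of -0.13 (camera adjusted p = 2.72e-09, adjusted p = 0.647 with an estimated correlation). RPS3A fell by 0.45 (SE 0.04) and RPL39 by 0.40 (SE 0.04). These are short transcripts, and 414 other coding genes matched to the ribosomal genes on length and GC content had a median of -0.10, while 481 matched to the respiratory genes had -0.11. The matched genes were longer, with medians of 1226 against 899 bases for the ribosomal genes and 1267 against 1000 for the respiratory genes. After correction for GC content and length the ribosomal median was 0.00, with 16 genes higher and 16 lower, which ended the call (camera adjusted p = 0.86). The respiratory median was then -0.06, with 7 genes higher and 18 lower (0.00264). Of 27 genes of the citric acid cycle 10 fell and 0 rose (11 and 1 adjusted over the list alone), SDHD of complex II by 0.36 (SE 0.04), and the list had a median of -0.11 (camera adjusted p = 0.000341, adjusted p = 0.454 with an estimated correlation). After the correction 5 fell, and the median was -0.03 (0.0241).

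Of 24 glycolysis genes, 9 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.0126, adjusted p = 0.454 with an estimated correlation). LDHA, which turns pyruvate into lactate, fell by 0.37 (SE 0.03), from 2466 ± 28.5 to 1903 ± 35.9 CPM, and the glycolytic kinase PGK1 by 0.30 (SE 0.04). Of 27 fatty acid oxidation genes 9 fell, among them the dehydrogenase HADH by 0.27 (SE 0.04), and 1 rose (11 and 1 adjusted over the list alone; camera adjusted p = 0.0237, adjusted p = 0.428 with an estimated correlation). This call ended without atezolizumab replicate 2 (0.0897) and after the correction (0.104). Of 27 hypoxia genes 12 fell and 2 rose (14 and 3 adjusted over the list alone), by a median of -0.25 (camera adjusted p = 2.88e-05, adjusted p = 0.428 with an estimated correlation). P4HA1, which hydroxylates collagen, fell by 0.43 (SE 0.07). Of 25 cholesterol synthesis genes 12 fell and 0 rose (15 and 0 adjusted over the list alone), by a median of -0.17 (camera adjusted p = 7.32e-07, adjusted p = 0.454 with an estimated correlation), with the sterol oxidase MSMO1 down by 0.53 (SE 0.08) and the isomerase IDI1 by 0.42 (SE 0.08). On the hypoxia and cholesterol lists atezolizumab replicate 2 had medians of -0.07 and -0.04, while replicate 1 had -0.25 and -0.23 and replicate 3 had -0.29 and -0.26. Without replicate 2, 18 hypoxia genes fell and 3 rose, by a median of -0.27, and 19 cholesterol genes fell and 1 rose, by a median of -0.25. Camera with an estimated correlation then gave adjusted p of 0.0919 and 0.13.

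Fibroblast markers fell in 8 of 15 cases and rose in 0 (10 and 0 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 1.14e-06, adjusted p = 0.138 with an estimated correlation). DCN and LUM, proteoglycans that bind collagen fibrils, fell by 0.80 (SE 0.19) and 0.72 (SE 0.13), and COL3A1 by 0.54 (SE 0.11). Replicate 2 stood apart on the marker list, with a median of -0.13 against -0.32 in replicate 1 and -0.33 in replicate 3, and without it 3 markers rose and 10 fell. The matrix lists were not called: of 21 collagen genes 0 rose and 2 fell (0 and 2 adjusted over the list alone), of 39 matrix glycoprotein and crosslinking genes 5 rose and 6 fell (7 and 6 adjusted over the list alone), and of 32 proteases and inhibitors 4 rose and 5 fell (5 and 5 adjusted over the list alone), with camera adjusted p = 0.847 for each. After correction for GC content and length 6 collagen genes fell and the first 2 of these lists were called lower (adjusted p = 0.000455 and 0.0445). Without replicate 2 none of the 3 was called, with 4 rising and 5 falling, 7 and 12, and 9 and 10 (0.738, 0.257 and 0.409). Of 11 pericyte and smooth muscle markers 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.23), with library medians of 0.29, 0.04 and 0.30. Without replicate 2, 4 rose and 0 fell, with a median of 0.33 (0.0201, adjusted p = 0.242 with an estimated correlation). In the TGF-beta and myofibroblast list 4 of 34 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.387), with medians of 0.09, -0.09 and 0.18 in replicates 1, 2 and 3. Without replicate 2, 10 rose and 7 fell and the list was called higher (0.0106, adjusted p = 0.262 with an estimated correlation). Those that rose included the matricellular genes CTGF by 0.66 (SE 0.09) and CYR61 by 0.34 (SE 0.05). Other falls with the largest change were those of the lipid transporter ABCA6 (-0.92, SE 0.24), SFRP2, which binds Wnt proteins (-0.89, SE 0.26), and the prostaglandin receptor PTGFR (-0.85, SE 0.15). The growth factor genes PGF and FGF5 moved apart, PGF at -0.75 (SE 0.17) and FGF5 at 0.54 (SE 0.11), in a list of 26 with 3 higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.884).

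Interferon response genes fell in 9 of 43 cases (15 adjusted over the list alone), with a negative change in all 43 and a median of -0.51 (camera adjusted p = 5.77e-11, adjusted p = 0.647 with an estimated correlation). IFI6 fell from 601 ± 32.4 to 332 ± 187 CPM, the ubiquitin-like ISG15 by 0.78 (SE 0.25) and the receptor transport gene RTP4 by 0.82 (SE 0.26). Antigen presentation and interferon-gamma genes fell in 14 of 38 cases (22 adjusted over the list alone), by a median of -0.41 (camera adjusted p = 4.74e-10, adjusted p = 0.514 with an estimated correlation), with the guanylate-binding protein GBP4 down by 0.90 (SE 0.27). Of the cytokine list 1 of 39 genes fell (0 adjusted over the list alone), TLR2, a receptor for bacterial lipoproteins, by 0.57 (SE 0.18), with a list median of -0.38 (camera adjusted p = 9.21e-05, adjusted p = 0.685 with an estimated correlation). Replicate 2 stood apart on all 3 lists, with medians of 0.02, -0.04 and 0.44, against -0.84, -0.54 and -1.34 in replicate 1 and -0.96, -0.58 and -1.89 in replicate 3. Without it, an alternative chosen after seeing the data, 43 of 43 interferon genes, 30 of 38 antigen presentation genes and 37 of 39 cytokine genes fell, with list medians of -0.90, -0.53 and -1.43 and adjusted p of 0.13, 0.0992 and 0.0526 with an estimated correlation. Of 17 immune checkpoint genes tested, 3 rose and 4 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.279), with a median of 0.07 in replicate 2 and -0.19 in each of the others. Without replicate 2, 3 of 18 rose and 7 fell and the list was called lower (0.00874, adjusted p = 0.13 with an estimated correlation). IDO1, which degrades tryptophan, fell by 0.95 (SE 0.28) and CD47, which wards off phagocytes, by 0.52 (SE 0.06), while the nectin-like PVR rose by 0.34 (SE 0.08).

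Cell cycle genes of G2 and M went both ways in atezolizumab, 4 higher and 13 lower of 41 (4 and 13 adjusted over the list alone; camera adjusted p = 0.0256, adjusted p = 0.708 with an estimated correlation). This call rested on replicate 2, whose median was -0.17, against -0.02 and -0.01 in replicates 1 and 3. Without it 10 rose and 12 fell (camera adjusted p = 0.878), after the correction 6 rose and 6 fell (0.829), and the call also ended without vehicle replicate 2 (0.0556) and with library totals (0.0551). The proliferation marker MKI67 rose by 0.48 (SE 0.11) and cyclin B1, CCNB1, fell by 0.31 (SE 0.03). S phase genes rose in 6 and fell in 6 of 42 cases (6 and 8 adjusted over the list alone). Unfolded protein response genes fell in 8 of 24 cases (12 adjusted over the list alone; camera adjusted p = 0.00288, adjusted p = 0.647 with an estimated correlation), among them the chaperone HSP90B1 by 0.26 (SE 0.04), and after the correction in 2 (0.0223). Replicate 2 had a median of -0.02 on this list, against -0.14 and -0.15 in replicates 1 and 3, and without it 14 fell and 0 rose. Immediate early genes rose in 8 of 35 cases and fell in 1 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0188, adjusted p = 0.685 with an estimated correlation). On that list replicate 2 had a median of 0.29, against 0.01 and -0.02 in replicates 1 and 3, and without it 8 rose and 10 fell (camera adjusted p = 0.671). Of 25 p53 targets, 2 rose and 6 fell (2 and 6 adjusted over the list alone), with the cyclin gene CCNG1 down by 0.43 (SE 0.04) and the death receptor FAS by 0.59 (SE 0.16; camera adjusted p = 0.0957). Without replicate 2, 3 rose and 10 fell and this list was called lower (0.000534, adjusted p = 0.256 with an estimated correlation). The thioredoxin reductase TXNRD1, of the oxidative stress list, rose by 0.37 (SE 0.07), 1 of 5 genes of 26 that rose, with 4 falling (7 and 6 adjusted over the list alone; camera adjusted p = 0.295). Without replicate 2, 10 rose and 4 fell (0.00827, adjusted p = 0.206 with an estimated correlation). Of 21 genes for making and desaturating fatty acids 1 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.179), and without replicate 2, 0 rose and 8 fell (0.00188, adjusted p = 0.13 with an estimated correlation).

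The atezolizumab counts moved with single libraries: 2241 genes without vehicle replicate 2 and 2378 without vehicle replicate 3. Correction for GC content and length left 2311 calls, 1839 of them shared with the 3801, and reads unique to 1 transcript gave 843. With the correction IDO1, GBP4, IFI6, RTP4, ISG15, PVR and ATF3 did not pass, and with unique reads ASNS did not and FAS changed sign. DESeq2 did not call IFI6 or ISG15. Of 50 called genes given for this comparison, between 39 and 41 kept their call without 1 vehicle library or without atezolizumab replicate 1 or 3. IDO1, GBP4, SFRP2, IFI6, RTP4, ISG15, TLR2, FAS and ATF3 lost it in each of these 5 fits, SCIN without atezolizumab replicate 1 or 3, and ABCA6 without vehicle replicate 1 or atezolizumab replicate 1. Groups did not overlap for 34.6% of genes, where chance gives 10% on average.

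Durvalumab cells had far lower transcript levels of inflammatory cytokines and interferon response genes than vehicle cells. They had higher levels of many genes of the ATF4 amino acid stress list, though the activity of ATF4 was not measured. Camera called these lists, and the calls were lost with an estimated correlation (adjusted p = 0.296 for each). IL6, an inflammatory cytokine, fell 7.84-fold, from 316 ± 43.1 to 40.3 ± 9.97 CPM (n = 3), and IL1B fell 6.86-fold, from 420 ± 66.0 to 61.2 ± 15.6 CPM. IFI27, an interferon-induced gene, fell 4.58-fold, from 47.2 ± 4.02 to 10.3 ± 3.99 CPM. SLC7A11 rose 2.20-fold, from 39.0 ± 1.75 to 85.8 ± 11.7 CPM, and ASNS 2.13-fold, to 33.4 ± 0.712 CPM. In all, 3011 genes passed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 1383 higher and 1628 lower, and 190 changed at least 2-fold, 45 up and 145 down.

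Of 39 genes of the cytokine list, 32 fell and 0 rose (37 and 0 adjusted over the list alone), with a median log2 change of -1.49 (camera adjusted p = 1.44e-22, adjusted p = 0.296 with an estimated correlation). The log2 changes were -3.16 for CXCL1 (SE 0.74), -2.75 for CXCL6 (SE 0.59) and -2.56 for CXCL3 (SE 0.68), which attract neutrophils. They were -3.09 for CCL7 (SE 0.65) and -2.68 for CCL2 (SE 0.70), which attract monocytes. CSF2, a growth factor for myeloid cells, fell by 2.76 (SE 0.75), and PTGS2, the inducible enzyme of prostaglandin synthesis, by 2.63 (SE 0.81). PI3, an elastase inhibitor that is not in this list, fell by 3.51 (SE 0.89). Adjusted p for these genes lay between 0.00902 (CCL7) and 0.0419 (PTGS2) by edgeR's quasi-likelihood test, whose estimate of the spread includes atezolizumab replicate 2. Without durvalumab replicate 3 neither these 8 genes nor IL6 and IL1B passed (adjusted p from 0.0513 to 0.147 by edgeR's quasi-likelihood test). PTGS2 and IL1B did not pass without any 1 of the 6 libraries of these groups (0.0741 to 0.147 and 0.0528 to 0.115), and CSF2 passed in 1 of these 6 fits, that without vehicle replicate 1. IL6, CCL2 and CXCL3 also did not pass without vehicle replicate 2 or 3 or durvalumab replicate 2, PI3 without vehicle replicate 3 or durvalumab replicate 2, and CXCL1 without durvalumab replicate 2. Without atezolizumab replicate 2, 37 of 39 genes fell (adjusted p = 0.0115 with an estimated correlation), and the SE for IL6 was 0.20 in place of 0.80. DESeq2 did not call PI3, CCL7, CSF2, CCL2 or CXCL3.

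Interferon response genes fell in 30 of 43 cases (41 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 8.83e-22, adjusted p = 0.296 with an estimated correlation). The antiviral membrane gene IFITM1 fell by 1.97 (SE 0.45), from 122 ± 4.55 to 31.1 ± 11.5 CPM. Antigen presentation and interferon-gamma genes fell in 27 of 38 cases (33 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 1.44e-22, adjusted p = 0.296 with an estimated correlation). The T cell attractant CXCL10 fell from 16.1 ± 0.65 to 4.46 ± 1.46 CPM and GBP4 by 1.47 (SE 0.28). Of 17 immune checkpoint genes, 7 fell and 3 rose (8 and 3 adjusted over the list alone; camera adjusted p = 0.0195, adjusted p = 0.317 with an estimated correlation), IDO1 by 1.14 (SE 0.28) and CD47 by 0.46 (SE 0.06) downward and PVR by 0.31 (SE 0.08) upward. Immediate early genes fell in 12 and rose in 5 of 35 cases (16 and 7 adjusted over the list alone; camera adjusted p = 0.00393, adjusted p = 0.429 with an estimated correlation), the nuclear receptor NR4A2 by 1.01 (SE 0.25) and the phosphatase DUSP6 by 0.64 (SE 0.16).

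**Figure D2:**
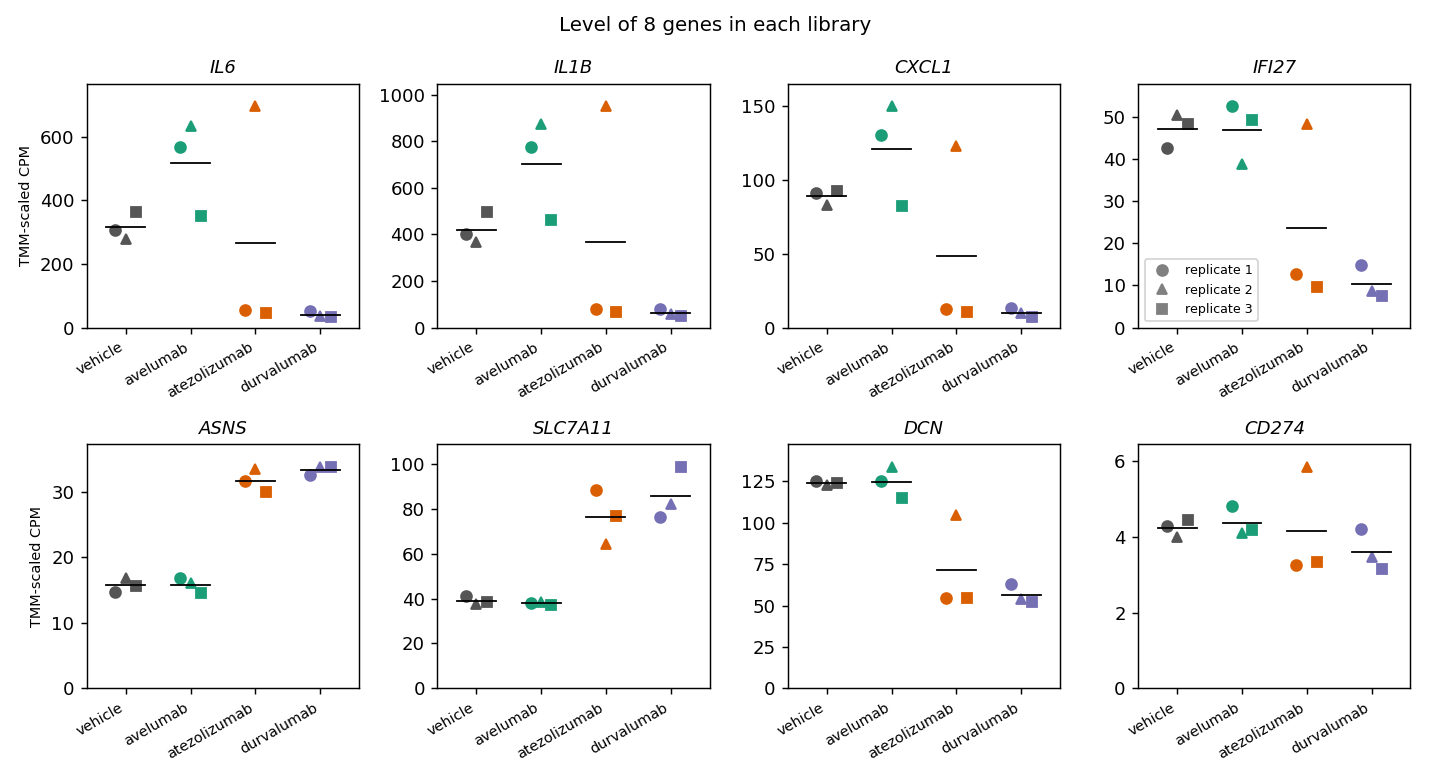
TMM-scaled CPM of 8 genes (vertical axes, from 0) in each of the 12 libraries (points, by group on the horizontal axis, with the symbol giving the replicate), where lines mark the mean of each group of 3 libraries. IL6 stands at 40.3 ± 9.97 CPM in durvalumab against 316 ± 43.1 in vehicle, and ASNS at 33.4 ± 0.712 against 15.7 ± 1.04.

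Among the 34 ATF4 genes, 18 rose and 3 fell in durvalumab (21 and 4 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 3.05e-15, adjusted p = 0.296 with an estimated correlation). PSAT1 rose by 0.80 (SE 0.06, adjusted p = 4.93e-05 by edgeR's quasi-likelihood test), while the stress hormone gene GDF15 fell by 0.73 (SE 0.21). In the oxidative stress list 7 of 26 rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0047, adjusted p = 0.309 with an estimated correlation), with TXNRD1 up by 0.51 (SE 0.07). Other genes with the highest rises were ADGRG6 (1.13, SE 0.23), SCIN (1.07, SE 0.17), the phospholipid flippase ATP8B1 (1.03, SE 0.20), KRTAP2-3 (0.90, SE 0.13), SAMD12 (0.88, SE 0.14), SLC4A4 (0.87, SE 0.15), S1PR1 (0.86, SE 0.14) and the kinase TNIK (0.84, SE 0.12).

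Fibroblast markers fell in 11 of 15 cases and rose in 0 (11 and 0 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 2.04e-11). This was the 1 list of 30 whose call held with an estimated correlation (adjusted p = 0.033). The complement proteases C1R and C1S fell by 1.26 (SE 0.27) and 1.13 (SE 0.23), and DCN fell from 124 ± 1.08 to 56.3 ± 5.70 CPM. Collagen genes fell in 6 of 21 cases and rose in 2 (12 and 2 adjusted over the list alone; camera adjusted p = 0.000861, adjusted p = 0.296 with an estimated correlation), COL3A1 by 0.83 (SE 0.10) downward and COL12A1 by 0.43 (SE 0.13) upward. Without atezolizumab replicate 2, 10 collagen genes fell and 2 rose. Of 39 matrix glycoprotein and crosslinking genes 14 fell and 3 rose (20 and 3 adjusted over the list alone; camera adjusted p = 0.000216, adjusted p = 0.296 with an estimated correlation), LUM by 0.87 (SE 0.13). In the protease list of 32 genes, 4 rose and 5 fell (4 and 7 adjusted over the list alone; camera adjusted p = 0.261), with the metalloprotease ADAMTS1 up by 0.73 (SE 0.10) and its class's inhibitor TIMP1 down by 0.77 (SE 0.17). Of 34 TGF-beta and myofibroblast genes 5 rose and 5 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.517), CTGF by 0.55 (SE 0.09) upward and smooth muscle actin, ACTA2, by 0.60 (SE 0.17) downward.

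Genes of the cholesterol synthesis list fell in 17 of 25 cases and rose in 0 (21 and 1 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 7e-10, adjusted p = 0.296 with an estimated correlation). INSIG1, which holds back sterol synthesis, fell by 0.57 (SE 0.15). Of 21 genes for making and desaturating fatty acids 4 fell and 0 rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.0313, adjusted p = 0.385 with an estimated correlation), the desaturases SCD by 0.59 (SE 0.13) and FADS2 by 0.58 (SE 0.12), and without vehicle replicate 3 this call ended (camera adjusted p = 0.0574). Hypoxia genes fell in 14 and rose in 2 of 27 cases (16 and 3 adjusted over the list alone; camera adjusted p = 1.21e-06, adjusted p = 0.296 with an estimated correlation). STC1, a secreted glycoprotein, fell from 408 ± 19.1 to 158 ± 14.4 CPM, and VEGFA, which drives vessel growth, by 0.53 (SE 0.14). Glycolysis genes fell in 10 and rose in 2 of 24 cases (12 and 3 adjusted over the list alone; camera adjusted p = 0.00321, adjusted p = 0.296 with an estimated correlation), with LDHA down by 0.28 (SE 0.03) and the hexokinase HK1 up by 0.27 (SE 0.05).

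Respiratory chain genes fell in 28 of 71 cases and rose in 0 (46 and 1 adjusted over the list alone), by a median of -0.12 (camera adjusted p = 4.09e-11, adjusted p = 0.296 with an estimated correlation), with NDUFA2 down by 0.34 (SE 0.05). Ribosomal protein genes fell in 28 and rose in 2 of 76 cases (31 and 3 adjusted over the list alone), by a median of -0.10 (camera adjusted p = 7.6e-06, adjusted p = 0.494 with an estimated correlation), with RPL24 down by 0.25 (SE 0.04). Genes matched on length and GC content had medians of -0.07 in both cases. After the correction the respiratory median was -0.04, with 3 genes higher and 10 lower (camera adjusted p = 0.0458), and the ribosomal call ended, with 15 genes higher and 10 lower and a median of 0.01 (0.507). Of 27 citric acid cycle genes 5 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.0916), DLST by 0.21 (SE 0.04) downward. Of 27 fatty acid oxidation genes 5 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.0447, adjusted p = 0.296 with an estimated correlation), with the carnitine transferase CPT1B down by 0.49 (SE 0.15). This call ended after the correction (0.222), with library totals (0.0934), and without atezolizumab replicate 2 (0.113), vehicle replicate 2 (0.0535) or 3 (0.0978), or durvalumab replicate 1 (0.0537) or 2 (0.0607). Unfolded protein response genes fell in 11 of 24 cases (17 adjusted over the list alone; camera adjusted p = 7.26e-06, adjusted p = 0.296 with an estimated correlation), the transcription factor XBP1 by 0.32 (SE 0.08) and the co-chaperone DNAJB9 by 0.45 (SE 0.14). Without atezolizumab replicate 2, 18 of these genes fell and 1 rose. Heat shock genes rose in 3 and fell in 1 of 20 cases (3 and 1 adjusted over the list alone; camera adjusted p = 0.474), with HSP90AA1 up by 0.22 (SE 0.05).

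Cell cycle genes were slightly higher in durvalumab, by a median log2 change of 0.05 for the G2 and M list and for the S phase list. Of 41 G2 and M genes 13 rose and 3 fell (14 and 4 adjusted over the list alone; camera adjusted p = 0.00393, adjusted p = 0.498 with an estimated correlation). S phase genes rose in 10 and fell in 1 of 42 cases (11 and 2 adjusted over the list alone; camera adjusted p = 0.0109, adjusted p = 0.429 with an estimated correlation). MKI67 rose by 0.37 (SE 0.11), the kinetochore gene CENPF by 0.38 (SE 0.11) and E2F8, a regulator of S phase genes, by 0.34 (SE 0.06). Of 25 p53 targets 9 fell and 1 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.000861, adjusted p = 0.296 with an estimated correlation), the cell cycle inhibitor CDKN1A by 0.42 (SE 0.10) and FAS by 0.77 (SE 0.16). Of 26 angiogenic and growth factor genes 2 rose and 6 fell (2 and 7 adjusted over the list alone; camera adjusted p = 0.473), EREG, a ligand of the EGF receptor, by 1.67 (SE 0.44) and PGF by 1.24 (SE 0.17) downward and FGF5 by 0.71 (SE 0.11) upward.

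Lists of markers of other cell types were tested as well. Of 9 endothelial markers 2 fell and 0 rose in durvalumab (3 and 0 adjusted over the list alone; camera adjusted p = 0.0414, adjusted p = 0.343 with an estimated correlation), PECAM1 from 3.78 ± 0.379 to 1.80 ± 0.398 CPM. Leaving out any 1 library of these groups, or atezolizumab replicate 2, ended this call, with camera adjusted p from 0.0545 to 0.127. Of 11 pericyte and smooth muscle markers 2 rose (4 adjusted over the list alone; camera adjusted p = 0.0414, adjusted p = 0.331 with an estimated correlation), the potassium channel regulator ABCC9 by 0.46 (SE 0.07). This call ended without vehicle replicate 2 (0.0809), durvalumab replicate 1 (0.0888) or 3 (0.0713), with library totals (0.0835) and after the correction (0.0524). Of 11 renal epithelial markers 2 rose and 0 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.974), with the keratin KRT19 at 2.06 ± 0.0923 against 1.12 ± 0.359 CPM. Of 5 myeloid markers 1 rose and 1 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.541), CD163 by 0.61 (SE 0.12) upward and CD14 by 0.76 (SE 0.21) downward. Lists with fewer than 5 tested genes had no list test. Of 4 B and plasma cell genes CD22 rose, from 4.34 ± 0.0456 to 5.91 ± 0.0902 CPM in durvalumab and 5.98 ± 0.203 in atezolizumab. Of 3 genes of the Fc receptor list TRIM21, a cytosolic antibody receptor, fell by 0.45 (SE 0.13) in durvalumab, and neither of the 2 T and NK cell genes, IL7R and CD247, passed in any comparison with vehicle. The list of 13 genes encoded in mitochondria had 0 members in the tables used here.

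The durvalumab count was moved by single libraries, to 1224 without vehicle replicate 2, 1119 without vehicle replicate 3, 1433 without durvalumab replicate 2 and 816 without durvalumab replicate 3. Scaled by library totals alone, 1839 genes were higher and 1313 lower, reads unique to 1 transcript gave 633 calls and the 6 libraries alone 4642. Of 71 called genes given for this comparison, 32 kept their call without durvalumab replicate 3, 41 without durvalumab replicate 2, 42 without vehicle replicate 3 and 47 without vehicle replicate 2, and all 71 kept it without atezolizumab replicate 2. Besides IL6, IL1B and the 8 genes given with the cytokine list, those that lost it without durvalumab replicate 3 were IFI27, IFITM1, CXCL10, IDO1, PVR, C1R, COL12A1, TIMP1, STC1, VEGFA, INSIG1, SCD, DNAJB9, XBP1, CDKN1A, FAS, GDF15, MKI67, CENPF, NR4A2, DUSP6, EREG, PECAM1, KRT19, HSP90AA1, ACTA2, CPT1B, TRIM21 and CD14, and no other gene given lost it when 1 library was left out. With the GC and length correction GDF15, CPT1B and TRIM21 did not pass, with unique reads ASNS did not, and there LDHA, FAS and DLST changed sign. Groups did not overlap for 41.4% of genes, where chance gives 10% on average.

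Atezolizumab and durvalumab shared much of their difference from vehicle, with 748 genes higher in both, 749 lower in both and 2 in opposite directions. Lists of these sizes drawn independently would share 139.1 and 182.6 genes. In 20 simulations all 12 libraries were redrawn without a change, and both groups were compared with the same redrawn vehicle libraries. These shared 0 genes, a number set in advance because unchanged genes rarely pass, so that it is no measure of the sharing. The log2 changes of both correlated at r = 0.687 across genes, against a mean of 0.501 in the simulations, and their covariance was 0.0294 against 0.00379. The simulated covariance already holds the part that shared controls give when genes vary independently. The 3 vehicle libraries are too few to split, so a further part from the shared controls was not tested. Vehicle carries the other file-name prefix, so a run difference could give the same sharing and cannot be told apart from the antibodies. No gene was called in 1 direction in all 3 antibodies by edgeR, where avelumab had 0 calls and 1674 genes at an unadjusted p under 0.05. DESeq2 gave 27 such genes and limma-voom 0.

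Compared directly, durvalumab and atezolizumab differed mainly in many small changes that followed the GC content of the transcripts. Immediate early genes fell in 10 of 35 cases in durvalumab against atezolizumab and rose in 0 (16 and 0 adjusted over the list alone), by a median of -0.23 (camera adjusted p = 5.95e-11, adjusted p = 0.671 with an estimated correlation). EGR1, an immediate early transcription factor, stood at 30.2 ± 2.68 against 62.7 ± 25.9 CPM (n = 3), and KLF2 and JUNB fell by 0.68 (SE 0.11) and 0.54 (SE 0.13). Atezolizumab replicate 2 stood apart on this list (0.29 against 0.01 and -0.02). Without it 9 fell and 0 rose, by a median of -0.13 (camera adjusted p = 1.78e-08, adjusted p = 0.196 with an estimated correlation). After correction for GC content and length the list call held (camera adjusted p = 2.37e-12), with a median of -0.17 and 0 genes called. G2 and M genes rose in 14 of 41 cases and fell in 0 (22 and 0 adjusted over the list alone), by a median of 0.14 (camera adjusted p = 1.09e-10, adjusted p = 0.671 with an estimated correlation), the mitotic kinase CDK1 by 0.31 (SE 0.06) and the topoisomerase TOP2A by 0.25 (SE 0.05). On this list too atezolizumab replicate 2 stood apart (-0.17 against -0.02 and -0.01). Without it 11 rose and 0 fell, by a median of 0.08 (camera adjusted p = 4.45e-07, adjusted p = 0.196 with an estimated correlation). After correction for GC content and length the list call held (camera adjusted p = 1.22e-08), with a median of 0.09 and 0 genes called. Of 39 cytokine genes 2 fell (28 adjusted over the list alone), by a list median of -1.08 (camera adjusted p = 3.25e-10, adjusted p = 0.697 with an estimated correlation), and IL6 stood at 40.3 ± 9.97 against 265 ± 374 CPM. Without atezolizumab replicate 2 the cytokine median was -0.09. COL6A1 of type VI collagen fell by 0.27 (SE 0.05), 1 of 4 collagen genes of 21 that fell, with 0 rising (7 and 0 adjusted over the list alone; camera adjusted p = 0.000393, adjusted p = 0.671 with an estimated correlation). After correction for GC content and length the collagen median went from -0.15 to -0.04, 0 collagen genes were lower and the list call ended (camera adjusted p = 0.273). Other large falls were those of the guidance cue NTN1 (-0.93, SE 0.27), GDF15 (-0.78, SE 0.20), the read-through gene PPAN-P2RY11 (-0.71, SE 0.17) and CITED4 (-0.70, SE 0.13). The largest rises were those of the kinase SGK3 (0.45, SE 0.12), TMEM117 (0.43, SE 0.12), SMIM11B (0.42, SE 0.09), SCOC (0.38, SE 0.10) and GRAMD1C (0.36, SE 0.09).

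In this comparison 1597 genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg), 890 higher and 707 lower, 11 of them at least 2-fold. Groups did not overlap for 28.8% of genes, where chance gives 10% on average. Across 11229 genes the log2 change correlated with GC content at r = -0.50, and after correction for GC content and length 3 genes passed. These were NACA, a ribosome-associated protein, at 0.26 (SE 0.04), RPL37 at -0.22 (SE 0.03) and SRSF4, a splicing factor, at -0.22 (SE 0.03), named after their values were seen because the count was small. None of the 16 other genes named for this comparison passed after the correction. With the 6 libraries of these groups alone edgeR called 0 genes. In the fit of all 12 libraries 4646 genes had an unadjusted p under 0.05, DESeq2 called 2495 and limma-voom 1600. With reads unique to 1 transcript SGK3, SMIM11B and TOP2A changed sign. The count was 220 without durvalumab replicate 1, 222 without replicate 2, 221 without replicate 3 and 994 without atezolizumab replicate 3. Of 17 called genes given for this comparison, 4 kept their call without durvalumab replicate 2 and 4 without durvalumab replicate 3.

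**Figure D3:**
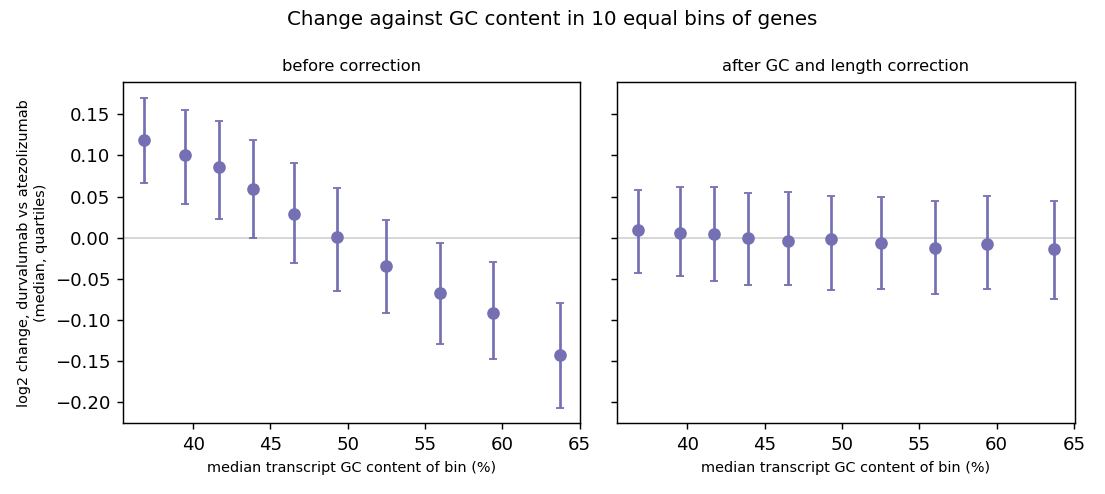
Median log2 change between durvalumab and atezolizumab (vertical axis) of genes in 10 bins by the GC content of their transcripts in percent (horizontal axis), with bars for the quartiles of each bin, before and after correction for GC content and length. The uncorrected medians run from 0.119 at 36.8% GC to -0.143 at 63.7% GC, and the corrected ones from 0.009 to -0.014.

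Avelumab differed from atezolizumab by lower amino acid stress genes and higher glycolysis, cholesterol synthesis and fibroblast genes, with list calls that were lost with an estimated correlation (adjusted p from 0.0985 to 0.332). ASNS stood at 15.8 ± 1.22 against 31.7 ± 1.75 CPM and SLC7A11 at 37.9 ± 0.818 against 76.5 ± 12.1 (n = 3), and 18 of 34 ATF4 genes were lower and 1 higher (21 and 2 adjusted over the list alone; camera adjusted p = 4.44e-22, adjusted p = 0.0985 with an estimated correlation). LDHA was higher by 0.33 (SE 0.03), with 10 of 24 glycolysis genes higher and 0 lower (15 and 1 adjusted over the list alone; camera adjusted p = 8.15e-07, adjusted p = 0.0985 with an estimated correlation). Cholesterol synthesis genes were higher in 10 of 25 cases and lower in 0 (18 and 1 adjusted over the list alone), by a median of 0.23 (camera adjusted p = 6.69e-11, adjusted p = 0.332 with an estimated correlation). Without atezolizumab replicate 2, 20 were higher and 1 lower, by a median of 0.33 (camera adjusted p = 0.0907 with an estimated correlation). Fibroblast markers were higher in 7 of 15 cases and lower in 0 (9 and 0 adjusted over the list alone), by a median of 0.18 (camera adjusted p = 1.77e-06, adjusted p = 0.0985 with an estimated correlation). Other genes with the largest differences were PGF (0.84, SE 0.16), DCN (0.81, SE 0.19), the granule proteoglycan SRGN (0.68, SE 0.11), IRAK3, which damps Toll-like receptor signals (0.66, SE 0.19), the glutamate transporter SLC1A3 (0.65, SE 0.15), ADGRG6 (-0.99, SE 0.23), KRTAP2-3 (-0.95, SE 0.13) and the potassium channel KCNH1 (-0.85, SE 0.20). The cytokine list had 1 of 39 genes higher (0 adjusted over the list alone) and a median of 0.76 (camera adjusted p = 3.04e-12, adjusted p = 0.45 with an estimated correlation). Without atezolizumab replicate 2 it had 37 higher (adjusted p = 0.0122 with an estimated correlation). In all 1887 genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg), 1003 higher and 884 lower, or 636 higher and 1401 lower when scaled by library totals alone. GC and length correction left 1225, the 6 libraries alone gave 7, and the count was 504 without avelumab replicate 2, 703 without avelumab replicate 1, 971 without atezolizumab replicate 1, 569 without atezolizumab replicate 3 and 4014 without atezolizumab replicate 2. DCN, SLC1A3, ADGRG6 and KCNH1 did not pass without avelumab replicate 1 or 2 or atezolizumab replicate 1 or 3, and IRAK3 without any of these or without avelumab replicate 3.

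Against durvalumab, avelumab cells had much higher cytokine transcripts and lower amino acid stress genes, with list calls that were lost with an estimated correlation (adjusted p = 0.225 for both). IL6 stood at 516 ± 149 against 40.3 ± 9.97 CPM, IL1B at 703 ± 214 against 61.2 ± 15.6 and CXCL1 at 121 ± 34.7 against 9.92 ± 2.97 (n = 3). Of 39 cytokine genes 37 were higher and 0 lower (37 and 0 adjusted over the list alone), by a median of 1.93 (camera adjusted p = 7.44e-31, adjusted p = 0.225 with an estimated correlation, 0.00485 without atezolizumab replicate 2). Interferon genes were higher in 21 of 43 cases (32 adjusted over the list alone; camera adjusted p = 8.66e-17, adjusted p = 0.29 with an estimated correlation), IFI27 by 2.19 (SE 0.47), and fibroblast markers in 11 of 15 (11 adjusted over the list alone; camera adjusted p = 2.32e-08, adjusted p = 0.0936 with an estimated correlation), C1R by 1.32 (SE 0.27). Without atezolizumab replicate 2, which is in neither group, 40 interferon genes were higher and 0 lower (camera adjusted p = 0.106 with an estimated correlation). Of 34 ATF4 genes 15 were lower and 2 higher (17 and 4 adjusted over the list alone), by a median of -0.15 (camera adjusted p = 1.2e-10, adjusted p = 0.225 with an estimated correlation). Other genes with the largest differences were PI3 (4.13, SE 0.88), the serpin SERPINB4 (4.02, SE 1.05), CCL8 (3.65, SE 0.87), SLC7A11 (-1.18, SE 0.11), ADGRG6 (-1.18, SE 0.23), ASNS (-1.08, SE 0.06), KCNH1 (-1.04, SE 0.20) and SCIN (-1.02, SE 0.17). In all 3155 genes passed (edgeR quasi-likelihood test, Benjamini-Hochberg), 1655 higher and 1500 lower, or 1201 higher and 2403 lower when scaled by library totals alone. The count was 1192 without durvalumab replicate 3, 1274 without avelumab replicate 1 and 1572 without durvalumab replicate 2. SERPINB4 did not pass without avelumab replicate 1 or any 1 durvalumab library, CCL8 and IL1B did not without durvalumab replicate 2 or 3, and IL6 did not without durvalumab replicate 3.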

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

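All tests of explanations in this part were chosen after the results they concern had been seen. Tested directly, 1597 genes differed between durvalumab and atezolizumab, 1887 between avelumab and atezolizumab, and 3155 between avelumab and durvalumab (edgeR quasi-likelihood test, Benjamini-Hochberg). After the GC and length correction the counts were 3, 1225 and 2863, and with the 6 libraries alone 0, 7 and 3743. Both comparisons with avelumab lie across the file-name prefixes, where a run difference cannot be told apart from the antibody. The splits of 6 libraries into 3 and 3 number 10 per comparison, too few for a share under 0.05. In the fit of all 12 libraries, 10 of the 10 splits of avelumab and vehicle gave the 0 calls reported. In each of the other comparisons 1 split of 10, the real one, reached the reported count, which was 3801 for atezolizumab and 3011 for durvalumab against vehicle. The highest other split called 0 genes for atezolizumab and for durvalumab against vehicle and for avelumab against durvalumab, 18 for durvalumab against atezolizumab, and 99 for avelumab against atezolizumab.

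Cytokine and interferon genes were lower in durvalumab and in 2 of 3 atezolizumab libraries. GC content or transcript length bias was argued against, since the median of the cytokine list in durvalumab was -1.50 after the correction and -1.49 before. Leukocytes in the vehicle cultures were tested as a source of the cytokine transcripts. The median of 36 leukocyte markers stood at 0.0057% of the IL1B level, and 28 of them lay below 0.5 CPM in vehicle. This median pools lymphocyte and myeloid markers, so it could stay low with myeloid cells alone and cannot exclude them. PTPRC, which encodes CD45, stood at 0.0276 CPM in vehicle against 420 CPM for IL1B, which argues against leukocytes as the main source. A run difference between both file-name prefixes may contribute: atezolizumab replicate 2 shares the prefix and stands at 0.44 above the vehicle mean, but 1 library cannot exclude it, and the prefixes are confounded with the antibodies. An effect of the antibodies stays open as well.

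Atezolizumab replicate 2 stood apart from its group. A swap with a vehicle or avelumab library was argued against, since 0 of those 6 libraries had the low cytokine level. A vehicle or avelumab library under its label was argued against, since its ATF4 list median was 0.35, where those libraries lay between -0.03 and 0.08. A mixture of a vehicle-like and an atezolizumab-like culture was argued against, since that median was 1.67 times the mean of replicates 1 and 3, and a mixture would lie below it. A sample from outside these groups and a difference between cultures stay open, and no biological explanation was tested.

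Many genes changed by small amounts. GC content bias may account for most calls between durvalumab and atezolizumab: 3 calls were left after the correction, the median absolute log2 change of the called genes went from 0.19 to 0.10 and the median SE from 0.045 to 0.040, so the calls ended because the changes shrank. In simulated data of this comparison, with a GC trend steeper than the real one, the correction cut calls made by the trend from 7204 to 2. It recovered 98 of 100 genes changed 2-fold, but only 11 of the 1597 real calls reached that size. Whether the correction also removes true changes of the smaller size called here was not tested. Transcript length bias may account for most of the lower ribosomal protein genes in atezolizumab, since matched genes had a median of -0.10. For the higher ATF4 genes in durvalumab such bias was argued against, with a list median of 0.20 after the correction and 0.18 before.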

How the results depend on the processing

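The alternatives chosen after seeing the data were the GC and length correction, the fit without atezolizumab replicate 2, and that fit with an estimated correlation. The causes of the differences below were not tested, except that fits of fewer libraries have fewer degrees of freedom and unique reads are fewer reads. Of 162 called gene results given in the text, all 162 kept their call and direction with median-ratio size factors and with either other filter, 161 with library totals, 153 with DESeq2, 158 with limma-voom, 136 with the GC and length correction, 125 with the 6 libraries alone, 154 with the replicate block and 157 without atezolizumab replicate 2. Leaving out another library, with the results of the comparisons it enters counted, 45 of 101 were kept without durvalumab replicate 3, 55 without replicate 2 and 84 without replicate 1. The numbers were 83, 88 and 100 of 121 without vehicle replicates 3, 2 and 1, 59 and 62 of 78 without atezolizumab replicates 3 and 1, and 18, 19 and 23 of 24 without avelumab replicates 1, 2 and 3. With unique reads 74 of 137 did, and 8 changed sign.

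Counts of genes changed moved as follows. For avelumab against vehicle (0), DESeq2 gave 71, no low-count filter 2, unique reads 1 and 2 groups only 5. For atezolizumab against vehicle, unique reads gave 843 and the GC and length correction 2311. For durvalumab against vehicle, unique reads gave 633 and 2 groups only 4642. Between durvalumab and atezolizumab, DESeq2 gave 2495, unique reads 271, the correction 3 and 2 groups only 0. Between avelumab and atezolizumab, unique reads gave 381, the correction 1225 and 2 groups only 7, and between avelumab and durvalumab unique reads gave 713. Genes called in all 3 antibodies numbered 0, with 27 by DESeq2 and 1 with 2 groups only.

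Leaving out 1 library at a time gave 0 to 11 genes for avelumab, 2241 to 5111 for atezolizumab and 816 to 4188 for durvalumab against vehicle, 220 to 2083 between durvalumab and atezolizumab, 504 to 4014 between avelumab and atezolizumab, 1192 to 4292 between avelumab and durvalumab, and 0 to 1 in all 3. In the same order of comparisons, lists called were 2 to 8, 14 to 18, 20 to 22, 10 to 19, 13 to 19 and 22 to 24. The CD274 change ranged from -0.037 to 0.081, -0.366 to 0.123, -0.36 to -0.143, -0.355 to 0.133, -0.083 to 0.406 and 0.183 to 0.399.

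Of the lists called by camera (5, 15, 23, 12, 15 and 23 in that order), an estimated correlation left 0, 0, 1, 0, 0 and 0, and without atezolizumab replicate 2 it left 0, 0, 2, 0, 1 and 2. Fry called 0, 10, 21, 3, 9 and 20 lists in that order. The GC and length correction left 2 for avelumab against vehicle. The direction of the ribosomal list reversed with that correction for avelumab (adjusted p = 0.701) and durvalumab (0.507) against vehicle and between them (0.803), all by camera, and without avelumab replicate 3 for avelumab, where leaving out 1 library gave 5.1e-06 to 0.955. Without atezolizumab replicate 2, the direction reversed for immediate early genes in atezolizumab against vehicle (camera adjusted p = 0.671, 0.846 with an estimated correlation) and between avelumab and atezolizumab (0.169 and 0.545), and between durvalumab and atezolizumab for interferon genes (0.00301 and 0.893) and antigen presentation genes (0.753 and 0.899). That library decides these directions. Leaving out 1 library at a time, camera adjusted p ran from 0.000137 to 0.671 and from 6.72e-05 to 0.169 for the immediate early genes, from 5.82e-09 to 0.237 for the interferon genes and from 1.46e-07 to 0.753 for the antigen presentation genes.

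With unique reads the log2 change of CD274 was -0.105 for avelumab and 0.147 for atezolizumab against vehicle and -0.252 between them, and the GC and length correction gave 0.034 for atezolizumab. Unique reads gave FAS 0.421 in atezolizumab and 0.33 in durvalumab, and LDHA 0.019 and DLST 0.172 in durvalumab, each against vehicle. They gave LDHA -0.026 between avelumab and atezolizumab, and SGK3 -0.039, SMIM11B -0.149 and TOP2A -0.07 between durvalumab and atezolizumab.

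The replicate numbers do not pair the libraries: the 18 correlations of same-numbered libraries ran from -0.53 to 0.24, 5 of them above 0.1, and 1 library correlated best with its own number. With the replicate block the counts of genes were 0, 3438, 2597, 815, 1524 and 2796 in the order above. The block ended the camera call of ribosomal genes for avelumab against vehicle (adjusted p = 0.0733) and between durvalumab and atezolizumab (0.0594), of fatty acid oxidation genes for durvalumab against vehicle (0.0553) and of immediate early genes between avelumab and atezolizumab (0.0517). The genes that lost their call were CPT1B and TRIM21 for durvalumab against vehicle and SGK3, TMEM117, GRAMD1C, NTN1, GDF15 and IL6 between durvalumab and atezolizumab. At these depths counting error is small for abundant genes.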

Other observations

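The tests in this part were chosen after seeing the data. Gene families, grouped by the stem of the symbol, were compared with all genes for their share of calls (206 families, Benjamini-Hochberg adjusted). In durvalumab against vehicle, 9 of 10 CXCL chemokine genes fell (Fisher's exact test, adjusted p = 4.03e-06), as did 12 of 25 HLA genes (0.000332). Of 12 genes with the stem IRF 8 fell, and 13 of 36 kinesin genes, KIF, rose (0.000498 for both). A stem can take in genes outside the family it names, so the IRF count is not that of interferon regulatory factors alone. In atezolizumab against vehicle, 23 of 49 genes for the large subunit of the mitochondrial ribosome, MRPL, fell (1.76e-06), as did 12 of 22 COX genes (0.000426) and 7 of 11 proteasome genes, PSMB (0.0088). Genes of a family are not independent, and MRPL, COX and PSMB transcripts are short, with median lengths of 1301, 1023 and 1015 bases. KIF transcripts are long, with a median of 5254 bases, and across genes the changes in durvalumab correlated with transcript length at r = 0.30.

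Without atezolizumab replicate 2, the count for avelumab against vehicle was 11 genes. Among them TNC, a matrix glycoprotein, rose by 0.34 (SE 0.05), HYOU1, a chaperone of the endoplasmic reticulum, by 0.20 (SE 0.03), and GDNF, a neurotrophic factor, by 0.23 (SE 0.04), named after their values were seen. In that fit IL6 fell in atezolizumab against vehicle by 2.67 (SE 0.23), IL1B by 2.52 (SE 0.24) and CXCL1 by 2.93 (SE 0.23).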
